A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

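mRNA levels were measured in the Saccharomyces cerevisiae wild-type strain YSBN6, grown in batch fermentors on minimal medium with 20 g/L glucose and 1 g/L glutamine at 30 °C, pH 5 and 1000 rpm. At an optical density near 1, rapamycin, a macrolide that inhibits the TOR complex 1 kinase, was added to 400 µg/L. Samples of 20 mL were quenched in cold methanol and extracted for total RNA, per the labels. Biotin-labelled RNA was hybridised to Affymetrix Yeast Genome 2.0 arrays, which carry probe sets for budding yeast and for the fission yeast Schizosaccharomyces pombe. There were 14 arrays from 3 fermentations, named BY005, BY006 and BY007. All 3 were sampled 10 min before the pulse (steady state) and at 7 and 24 min after it, and BY005 alone also at 3, 10, 14, 56 and 120 min. Each fermentation was a separate culture, and the labels call the replicates biological.

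The deposited values are RMA intensities, made by the authors with the package affy in R 2.10.0, per the submitters' processing notes. RMA joins background correction, quantile normalization and probe set summary in one step, and it makes the arrays' overall distributions alike. The intensities were on a linear scale, with a median over genes between 1591 and 1776 per array, so log2 was taken first. The test had been fixed for log2 values and was otherwise run as planned. No scanner files, detection calls or scan batches were used here. The precision is limited by the number of arrays.

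Of 10928 probe sets, 5498 had exactly 1 budding yeast gene in the platform annotation and gave 5449 genes, 47 of them as the mean of more than 1 probe set. Another 1746 probe sets had 1 gene of fission yeast, 1 had several genes, 213 were controls or reporters and 3470 had no gene in the annotation used here. Symbols were updated through the gene ID for 12 genes, with a gene table of assembly R64. Of the protein-coding genes of that table, 9.55% had no gene-specific probe set. A suffix that marks probes shared with other genes stood on 128 of the single-gene probe sets. The fission yeast probe sets, which should not bind budding yeast RNA, gave the background: their median was 4.44 and their 95th percentile 5.63 on the log2 scale. The median gene at steady state lay at 10.71 and the brightest at 14.84, and 121 genes had a mean below the background percentile. Where the mean of a gene lay below it in one of the groups compared, the fold is given as "at least", against 5.63. At the bright end, 156 genes lay within 1 log2 unit of the top at steady state, where a rise, and possibly a fall, can be understated.

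Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 14 arrays in 8 time groups, with no block. The residual degrees of freedom were 6 and the prior added 2.43. Benjamini-Hochberg adjustment ran over the 5449 genes, and a gene counted as changed at an adjusted p under 0.05. All p-values of single genes below are such adjusted values, and errors after ± are the fit's standard errors unless named otherwise. At times with 1 array the spread came from the replicated times, so the lone array was assumed to vary like those. Such a difference has no replicate check of its own. On simulated arrays with known changes, log2 changes of 0.5, 1 and 2 were recovered for 80.6%, 95.5% and 100% of the genes in the comparison at 7 min, with 12 false calls among 196. The same sizes were recovered for 82.1%, 98.5% and 100% at 24 min and for 53.7%, 86.6% and 98.5% at 3 min. The simulated changes fell on randomly drawn genes and were equal on all arrays of a time. Real changes at 7 min differed in size between the fermentations, so these shares do not tell how many real changes were found.

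There were 26 gene lists, fixed before the data were examined. Each was tested with limma's camera with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera was repeated with the correlation estimated from the residuals. Fry, which tests a list against no change rather than against the other genes, was run as another test. No list passed camera with an estimated correlation in any comparison. At times with 1 array, a list's median is given with its percentile among 10000 random lists of the same size and mean expression. That percentile takes no account of members that move together or of variation between arrays, so it is not a test. The lists of cytosolic and mitochondrial ribosomal proteins were drawn by name pattern, so RPP1, a subunit of nuclear RNase P, stands in the first, and MRP8, which is not known here as a ribosomal subunit, in the second. Of the list members, the rapamycin receptor gene FPR1, the urea amidolyase gene, TDH2 and 10 cytosolic ribosomal protein genes were among those with no gene-specific probe set and were not analysed here.

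The genes named in the text follow a rule fixed in advance. It takes the 10 largest rises and falls at 7 and at 24 min, and the 5 largest each way for 24 against 7 min and for the arrays at 3 and 120 min. Such a gene had to pass the threshold, move the same way in all fermentations sampled and have a gene name. The rule adds up to 4 members of each list by their change at 24 min and the fixed genes GAP1, MEP2, DAL80, CIT2, CTT1, HSP12, TOR1, GLN3, MSN2, SFP1 and ACT1. Other genes are named only where the text says that they were chosen after their values were seen.

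Samples of one fermentation came from the same culture, so the fermentation pairs them. Their deviations from the time means correlated across genes with r = 0.428, 0.075 and 0.344 between steady state and 7 min in BY005, BY006 and BY007, and with r = 0.528, 0.12 and 0.359 between steady state and 24 min. Between 7 and 24 min they were 0.063, -0.164 and 0.415. Between different fermentations these correlations ran from -0.519 to 0.399. Only the values of BY005 with steady state and that of BY007 between 7 and 24 min lay above this range. The pairing thus showed in part, and not in BY006. The fit with the fermentation as a block was an alternative. The other alternatives were arrays centred on the gene median, quantile normalization of the genes alone, dim genes or shared probe sets left out, the brightest probe set per gene, a trended and robust variance prior, a 2-fold minimum, and each array left out in turn. Scaling to the poly-A spike-in probe sets, a spread from the compared arrays alone and a spread without the 7 min arrays were added after seeing the data. The spike-in scaling left out the 7 min array of BY005, whose spike-in signal of 4.70 (log2) lay near background, against 8.65 to 9.96 on the other arrays. The labels do not say how the spike-ins were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.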

Results

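Transcript levels were followed in glutamine-grown yeast before and after a pulse of rapamycin, which inhibits TOR complex 1, to see in which order groups of genes changed. None of the 14 arrays came from a culture left without rapamycin after the steady-state sample. Effects of time in batch culture or of the pulse itself therefore cannot be told apart from those of rapamycin. There were 3 arrays at steady state, 3 at 7 min, 3 at 24 min, and 1 each at 3, 10, 14, 56 and 120 min. The values were RMA intensities of 5449 genes, compared as log2 differences against steady state. The median gene had an SD of 0.0672 among the steady-state arrays, 0.0904 at 7 min and 0.0821 at 24 min (log2, n = 3 arrays each). Replicate arrays of one time correlated across genes with r of at least 0.989. The first principal component held 79.5% of the variance and the second 10.4%; on the first, the 3 min array lay with the steady-state arrays. Hybridisation controls ran from 8.42 to 11.67 and rRNA probe sets from 11.57 to 13.08 (log2), and both varied within the replicated times. The difference between the 3' and 5' probe sets of ACT1, a measure of RNA integrity, lay between 0.59 and 0.83 on all 14 arrays.

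**Figure D1:**
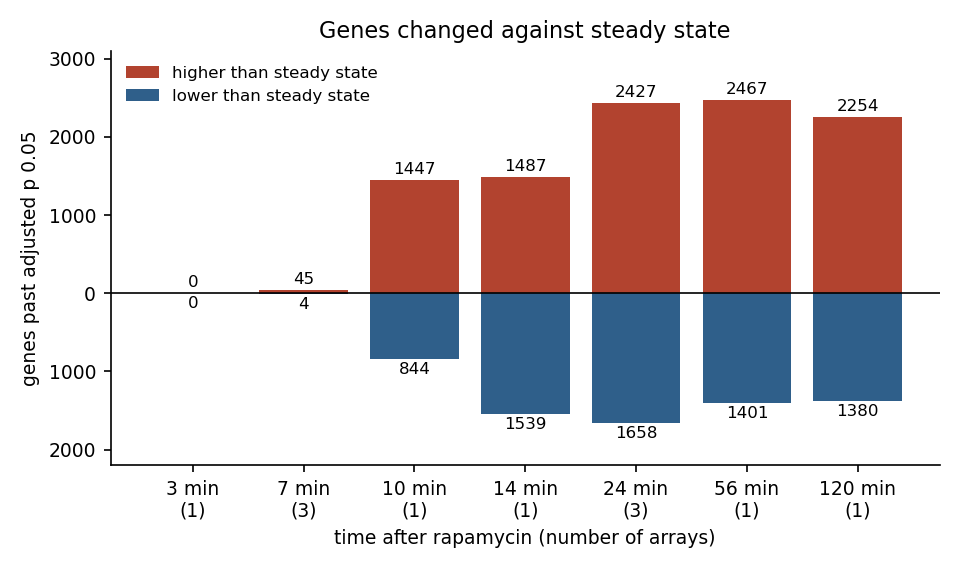
Number of genes past an adjusted p of 0.05 (limma, Benjamini-Hochberg) above and below the steady state at each time, with the number of arrays in parentheses. No gene passed at 3 min, 49 passed at 7 min and 4085 at 24 min, and times with 1 array have no replicate check of their own.

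At 3 min no gene passed the threshold. In the single array from BY005, DAL80, which encodes a GATA repressor of nitrogen catabolite genes, read 0.83 ± 0.52 above steady state (adjusted p = 0.93). MEP2, for an ammonium permease, read 0.20 ± 0.12 (adjusted p = 0.93) and SPS4, a sporulation gene, 0.33 ± 0.12 (adjusted p = 0.92). With limma, 0 genes passed and 287 had an unadjusted p under 0.05, and the smallest adjusted p was 0.885. In 25 of the 26 lists no member passed when adjusted over the list alone either. The exception was the reference genes, where 1 of 6 members rose when adjusted over the list alone: TAF10, a subunit of TFIID and SAGA, at 0.37. The nitrogen catabolite repression list had a median of 0.12, above all 10000 random lists, in the fit against the mean of the 3 steady-state arrays. Against the steady-state array of BY005 itself it was 0.05, and with spike-in scaling -0.00. DAL80 stood at 9.67 (log2) at 3 min, against 9.28, 8.91 and 8.32 at steady state in BY005, BY006 and BY007.

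At 7 min, genes for the uptake and breakdown of poor nitrogen sources had risen in all 3 fermentations. The allantoin permease gene DAL4 (YIR028W) rose 8.16-fold (3.03 ± 0.54 log2, adjusted p = 0.049, 3 against 3 arrays) and DAL80 (YKR034W) rose 7.74-fold (2.95 ± 0.37, adjusted p = 0.013). DIP5 (YPL265W), a permease for glutamate and aspartate, rose 5.69-fold (2.51 ± 0.22, adjusted p = 0.0038), and PUT4, the proline permease, rose 4.89-fold (2.29 ± 0.39, adjusted p = 0.043). The other rises in the top 10 were the allantoinase gene DAL1 (4.13-fold), the urea transporter gene DUR3 (3.92-fold), the allantoate permease gene DAL5 (3.86-fold), MPC3 of the mitochondrial pyruvate carrier (3.85-fold), the allantoicase gene DAL2 (3.56-fold) and RTS3 (3.04-fold), a presumed subunit of a protein phosphatase complex. Among the fixed genes, MEP2 rose by 0.69 ± 0.09 (adjusted p = 0.014), while the general amino acid permease gene GAP1 read 0.34 ± 0.09 higher (adjusted p = 0.11). Few genes fell. MET8 (-0.54 ± 0.07, adjusted p = 0.014) and MET1 (-0.52 ± 0.08, adjusted p = 0.04), enzymes of siroheme synthesis for sulfite reductase, were the named falls together with DUG3 (-0.34 ± 0.06, adjusted p = 0.043), which takes part in glutathione breakdown. The remaining fall, chosen after its value was seen, was the unnamed YKL068W-A (-0.62 ± 0.09, adjusted p = 0.023). MET1 passed no longer with the fermentation as a block (adjusted p = 0.05), and DUG3 turned to 0.05 with spike-in scaling.

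In total 45 genes rose and 4 fell at 7 min (limma, adjusted p under 0.05), of which 24 and 0 by at least 2-fold, while 1092 had an unadjusted p under 0.05. Blocking on the fermentation gave 109 rises and 9 falls, 118 genes in all. With the block 9 more named genes passed, among them the oligopeptide transporter gene OPT2 (adjusted p = 0.04), the guanine deaminase gene GUD1 (adjusted p = 0.034) and GPG1 (adjusted p = 0.024). Quantile normalization of the genes alone gave 25 rises and 6 falls. The count rested on single arrays. It was 765 (589 rises and 176 falls) without the 7 min array of BY006, 30 without that of BY005 and 7 without that of BY007, and it was 11, 8 and 8 without the steady-state arrays of BY005, BY006 and BY007. DIP5 and SPS4, up by 1.01 ± 0.09 (adjusted p = 0.0038), passed with each of these arrays left out. DAL80 missed the threshold without the steady-state array of BY006 (adjusted p = 0.071) or BY007 (adjusted p = 0.07) and without the 7 min array of BY007 (adjusted p = 0.061).

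**Figure D2:**
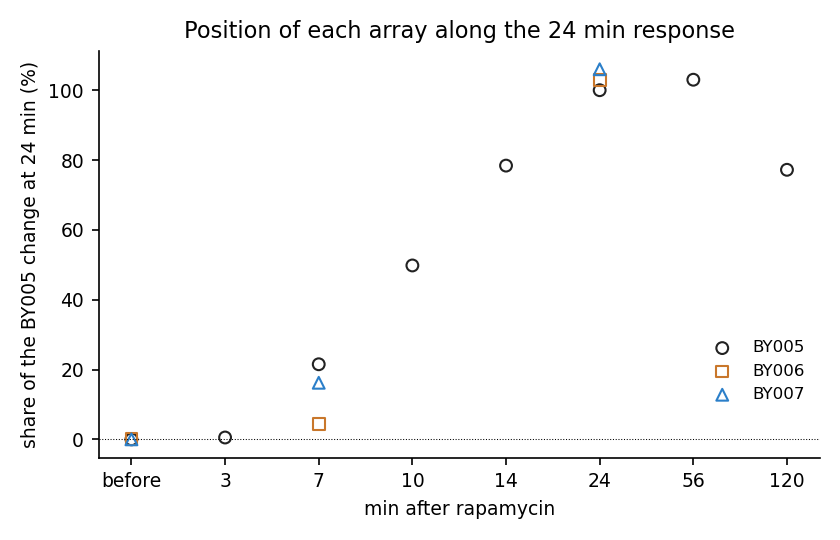
Distance of each array along the change of BY005 from steady state (0%) to 24 min (100%), by minutes after rapamycin and fermentation. At 7 min BY006 stood at 4.44% and BY005 at 21.5%, while at 24 min all 3 stood between 100% and 106%.

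By list, 16 of 30 measured nitrogen catabolite repression genes rose at 7 min and none fell, and 27 rose when adjusted over the list alone. Their median was 0.88 (camera adjusted p = 6.6e-23, but adjusted p = 0.33 with an estimated correlation). In the single fermentations that median was 1.21, 0.58 and 0.89 for BY005, BY006 and BY007. No member of the stress response list, targets of Msn2 and Msn4, passed over all genes, while 18 of 30 rose when adjusted over the list alone, with a median of 0.44. In the single fermentations the stress response median was 0.68, 0.12 and 0.52 and that of trehalose and glycogen 0.82, 0.11 and 0.52, lowest in BY006. Likewise 15 of 17 trehalose and glycogen genes rose when adjusted over the list alone (median 0.52), 11 of 31 autophagy and vacuolar protease genes (median 0.23), 4 of 7 retrograde response genes (median 0.33) and 1 of 20 heat shock factor targets (median 0.09), against 0 over all genes in each. Of the meiosis and sporulation genes, 1 of 18 rose (SPS4) and 5 when adjusted over the list alone (median 0.24). With quantile normalization of the genes alone this median was 0.07. Against its own steady state BY005 already stood at 0.20 in this list at 3 min, and at 0.36 at 7 min. In the respiratory chain list none of 36 members passed either way (median 0.09). Camera placed these 7 lists above the other genes. Its adjusted p was 1e-08 for stress response, 7.6e-07 for trehalose and glycogen, 0.0012 for autophagy, 0.009 for retrograde response, 0.046 for heat shock factor targets, and 0.017 for both meiosis and the respiratory chain. With an estimated correlation none passed: adjusted p = 0.55 with an estimated correlation for heat shock factor targets, 0.58 for the respiratory chain and 0.52 for the others. The block ended the call of the heat shock factor targets (adjusted p = 0.11), as did leaving out the 7 min array of BY007 (adjusted p = 0.18), of BY006 (adjusted p = 0.074) or the steady-state array of BY006 (adjusted p = 0.078) or BY007 (adjusted p = 0.096). The call of the respiratory chain ended without the 7 min array of BY005 (adjusted p = 0.19) or the steady-state array of BY007 (adjusted p = 0.22). With spike-in scaling the calls of the heat shock factor targets (adjusted p = 0.5) and of the respiratory chain (adjusted p = 0.63) were lost.

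Camera placed 6 lists below the other genes at 7 min, but none of them passed with an estimated correlation. Each of their medians turned positive with spike-in scaling, which raised the median of all genes by 0.36. That shift was smaller than the scaling's median standard error of 0.43 per gene. The scaling also left out the 7 min array of BY005, on which ribosome biogenesis was lowest, so it does not settle the sign. Ribosome biogenesis had a median of -0.25 (adjusted p = 3e-18; 0.20 with spike-in scaling), RNA polymerase I and III -0.18 (adjusted p = 1e-08; 0.22), and sulfur assimilation -0.27 (adjusted p = 1.2e-14; 0.14). Cytosolic ribosomal proteins (-0.03, adjusted p = 1.3e-07; 0.35 with spike-in scaling), translation factors (-0.03, adjusted p = 9.5e-05; 0.34) and purine and one-carbon genes (-0.04, adjusted p = 0.0014; 0.33) lay close to 0. In the single fermentations BY005, BY006 and BY007 the median was -0.40, 0.03 and -0.36 for ribosome biogenesis, -0.34, 0.00 and -0.25 for the polymerases, and -0.09, 0.01 and -0.03 for purine and one-carbon genes, so BY006 was not lower in these. In sulfur assimilation it was -0.21, -0.25 and -0.16. With spike-in scaling the calls of translation factors (adjusted p = 0.058) and purine genes (adjusted p = 0.15) were lost, and amino acid permeases were called higher (adjusted p = 4.2e-05). For these 6 lists the adjusted p with an estimated correlation was 0.52, 0.51, 0.078, 0.52, 0.33 and 0.52, in the order given. Single members passed only in sulfur assimilation, where 2 of 22 fell, MET8 and MET1, and 8 fell when adjusted over the list alone. In each of the other 5 lists 0 members passed either way, and RPL22B, which encodes a ribosomal protein, read -0.43 ± 0.12 (adjusted p = 0.12). The remaining 12 lists were not called at 7 min, and for 7 of them the median and camera's direction differed in sign. Of their members, DIP5 rose among the 13 amino acid permeases and NPR1, a kinase that regulates permeases, among the 29 TOR pathway genes (0.56 ± 0.06, adjusted p = 0.01).

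At 24 min, 75% of the genes had changed, and 4 of the 10 named top rises at 7 min, DAL4, DAL80, PUT4 and DAL5, were again among the top 10. DAL4 was up 99.5-fold (6.64 ± 0.54, adjusted p = 6.3e-06, 3 against 3 arrays) and OPT2 up 49.1-fold (5.62 ± 0.22, adjusted p = 1.2e-07). MLS1, the malate synthase of the glyoxylate cycle, rose 36-fold (5.17 ± 0.23, adjusted p = 2e-07), UGA4, the GABA permease, 34.3-fold (5.10 ± 0.40), and GDH3, a glutamate dehydrogenase, 30-fold (4.91 ± 0.24). MLS1 started near the background percentile, at 5.93, 5.44 and 5.77 at steady state in BY005, BY006 and BY007. The top 10 was completed by DAL80 (27.3-fold), PUT4 (25.9-fold), GUD1 (25.9-fold), DAL5 (23.2-fold) and the zinc finger gene LEE1 (22.6-fold). GAP1 rose by 0.90 ± 0.09 (adjusted p = 2.7e-05) and MEP2 by 1.32 ± 0.09 (adjusted p = 1.8e-06), and both lay within 1 log2 unit of the top of the range. Of 30 nitrogen catabolite repression genes 28 rose and 2 fell, with the same counts when adjusted over the list alone. The falls were the permease genes AGP1 (-0.42 ± 0.06, adjusted p = 0.00031) and MEP3 (-0.58 ± 0.06, adjusted p = 2.7e-05), looked up after the count was seen. The list's median was 2.24 (camera adjusted p = 1.1e-06, but adjusted p = 0.43 with an estimated correlation).

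The largest falls at 24 min were of genes for making ribosomes. UTP13 (YLR222C), of the small-subunit processome, fell from 11.64 ± 0.01 to 5.11 ± 0.96 (mean log2 ± SD, n = 3), at least 64.3-fold lower because it ended below background (adjusted p = 1.2e-06). NOC2, PWP2 and UTP8, which act in pre-ribosome assembly and export, also ended below background and were at least 51.7-fold, 36-fold and 36.2-fold lower. DBP3, an RNA helicase, fell 66.7-fold (-6.06 ± 0.31, adjusted p = 4.4e-07) and RPA49, a subunit of RNA polymerase I, 61.7-fold (-5.95 ± 0.27, adjusted p = 2.4e-07). In BY006 and BY007 both ended near or below the background percentile (DBP3 5.52 and 5.36, RPA49 5.63 and 5.37), so these folds may be understated. RLP24, PUF6, RPF2 and NSR1, all factors of ribosome assembly, fell 58.4-fold, 57.4-fold, 51.4-fold and 50.4-fold. Of 99 ribosome biogenesis genes 98 fell, also when adjusted over the list alone, with a median fall of 15.5-fold and medians of -3.75, -4.16 and -4.14 in BY005, BY006 and BY007. All 20 RNA polymerase I and III genes fell (median 6.11-fold), among them RPA34 (-4.53 ± 0.19), RPA43 (-4.49 ± 0.18) and RPA190 (-3.63 ± 0.18). Of 30 translation factor genes 26 fell and 1 rose (median -0.83), with TIF4631 (-2.61 ± 0.05), of initiation factor eIF4G, and NIP1 (-2.30 ± 0.12), of eIF3, among the falls. The camera adjusted p was 3.7e-33, 1.5e-11 and 7.3e-09 for these 3 lists, and adjusted p = 0.32, 0.32 and 0.22 with an estimated correlation.

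Cytosolic ribosomal protein genes fell at 24 min too, but by little. Their median level at steady state was 14.08 (log2), near the top of the range, where a fall may be understated. Of 128 measured, 120 fell and 0 rose over all genes, and 122 fell when adjusted over the list alone, with a median of -0.35, or 1.27-fold. Among the named members RPL22B fell 15.2-fold (-3.93 ± 0.12, adjusted p = 5.7e-08), RPS9A 8.32-fold (-3.06 ± 0.13) and RPS14B 4.14-fold (-2.05 ± 0.08). RPP1, the RNase P gene caught by the name pattern, fell 4-fold. RPS26B, of the small subunit, was 1.6-fold lower (-0.68 ± 0.05, adjusted p = 4.5e-06). With spike-in scaling the median stayed negative at -0.06 and 11 of the genes fell. The camera adjusted p was 8.6e-20, and adjusted p = 0.36 with an estimated correlation. Purine and one-carbon genes fell in 13 of 16 cases and rose in none, also over the list alone (median -0.92, camera adjusted p = 7.2e-07, adjusted p = 0.32 with an estimated correlation). IMD4, an IMP dehydrogenase of guanine nucleotide synthesis, fell 9.61-fold and ADE4, which starts purine synthesis, 3.21-fold.

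**Figure D3:**
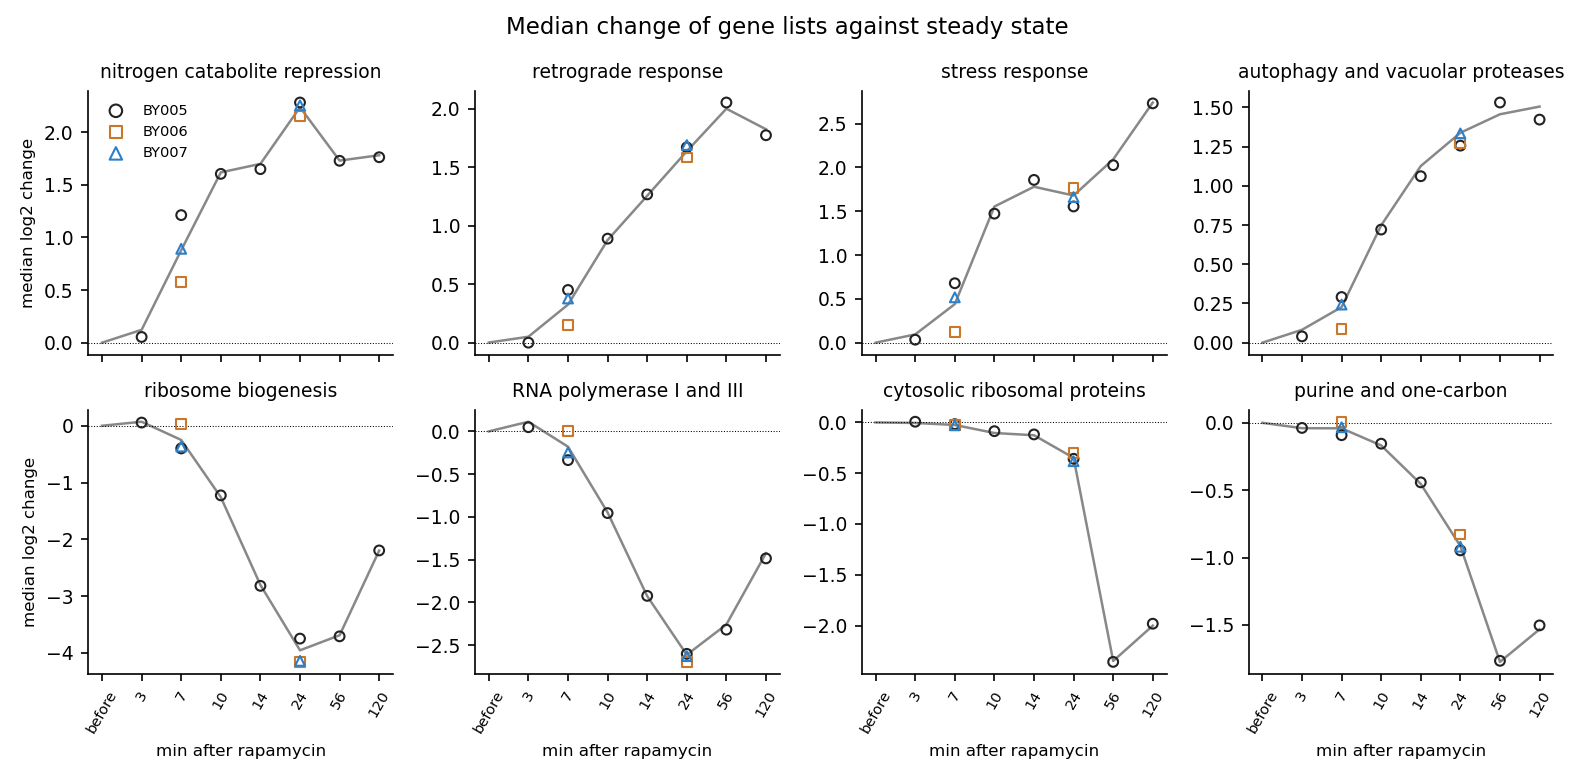
Median log2 change of 8 gene lists by time after rapamycin (lines: fitted change against the 3 steady-state arrays; symbols: each array against its own fermentation's steady state), with ribosome biogenesis at -3.95 and ribosomal proteins at -0.35 at 24 min, and at -3.69 and -2.35 at 56 min. With spike-in scaling the 4 lower lists turn positive at 7 min, ribosomal proteins and purine genes also at 14 min, and the 4 upper lists, ribosome biogenesis and the polymerases turn negative at 3 min.

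All 30 stress response genes rose at 24 min (median 3.2-fold). MOH1, of a conserved family of unknown function, rose 10.4-fold (3.38 ± 0.26, adjusted p = 4.6e-06), DCS2, a regulator of mRNA decapping, 7.28-fold, and CTT1, the cytosolic catalase, 7.04-fold (2.81 ± 0.34, adjusted p = 6.9e-05). HSP12, a membrane-protecting stress protein, rose 1.59-fold near the top of the range. All 17 trehalose and glycogen genes rose (median 2.26-fold), including the glycogen phosphorylase gene GPH1 (7.21-fold) and the debranching enzyme gene GDB1 (5.01-fold). GAC1, a phosphatase subunit for glycogen synthase, was below background at steady state and at least 5.14-fold higher. Of 31 autophagy and vacuolar protease genes 27 rose and 2 fell (median 2.53-fold), among the rises ATG8, whose product coats autophagosomes (4.75-fold), the aminopeptidase gene APE1 (4.4-fold) and the proteinase B gene PRB1 (4.28-fold). All 7 retrograde response genes rose (median 3.11-fold), led by the peroxisomal citrate synthase gene CIT2 (6.23-fold, 2.64 ± 0.15, adjusted p = 8.3e-07), ACO1 (3.69-fold), IDH2 (3.34-fold) and CIT1 (3.11-fold) of the citric acid cycle. All 32 proteasome genes rose by a little (median 1.32-fold), such as RPN10 (0.59 ± 0.06) and PRE3 (0.57 ± 0.05). These counts were the same when adjusted over the list alone.

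Camera called these 5 lists higher at 24 min, with adjusted p of 2.9e-07, 6.6e-05, 1.4e-05, 0.0013 and 1.4e-05 in the order given, and adjusted p = 0.43 with an estimated correlation for each. Of 36 respiratory chain genes 31 rose and 2 fell (32 rose when adjusted over the list alone), with the succinate dehydrogenase gene SDH1 up 2.45-fold and the Rieske protein gene RIP1 up 2.02-fold (camera adjusted p = 3e-04, adjusted p = 0.43 with an estimated correlation). With spike-in scaling the camera calls of the proteasome (adjusted p = 0.18) and of the respiratory chain (adjusted p = 0.11) were lost. Of 18 meiosis and sporulation genes, markers of another cell state, 13 rose and 1 fell, also over the list alone (median 0.84, camera adjusted p = 0.032, adjusted p = 0.43 with an estimated correlation). HOP1, of the meiotic chromosome axis, was below background at steady state and at least 4.36-fold higher, SPS4 rose 3.57-fold, the meiotic recombinase gene DMC1 3.47-fold and the meiotic regulator gene NDT80 2.37-fold.

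The other 13 lists were not called at 24 min (camera adjusted p from 0.1 to 0.64), and their members went both ways or moved little. Of 13 amino acid permeases 5 rose and 8 fell (median -0.64). GNP1, for glutamine, fell 11.7-fold (-3.55 ± 0.06, adjusted p = 2.3e-08), and BAP2 and BAP3, for branched-chain amino acids, fell 8.48-fold and 6.39-fold, while DIP5 stood 11.4-fold higher. Of 22 sulfur assimilation genes 6 rose and 11 fell, with a median of -0.17 that turned to 0.11 with spike-in scaling. MUP1, the methionine permease, fell 10.4-fold and SUL1, a sulfate permease, rose 2.8-fold. Without the 24 min array of BY006 this list was called (adjusted p = 0.046). Of 33 amino acid biosynthesis genes 8 rose and 14 fell, with a median of -0.08 that turned to 0.20 with spike-in scaling. LEU9, of leucine synthesis, fell 5.56-fold, ARG8 of arginine synthesis fell 1.83-fold, and ORT1, the mitochondrial ornithine carrier, rose 1.96-fold. Among 29 TOR pathway genes 16 rose and 7 fell. MSN4 (1.67 ± 0.14), NPR1 (1.01 ± 0.06), NPR2 (1.00 ± 0.08) and TOR1 (0.38 ± 0.07, adjusted p = 0.00074) rose, and IFH1, a coactivator of ribosomal protein genes, fell by 1.83 ± 0.13.

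SFP1, a transcription factor for ribosome biogenesis genes, fell by 0.37 ± 0.06, and GLN3, the GATA activator itself, read -0.12 ± 0.06 (adjusted p = 0.12). MSN2 rose by 0.14 ± 0.05 (adjusted p = 0.03), a call lost without the steady-state array of BY006 (adjusted p = 0.1) or BY007 (adjusted p = 0.056) or without the 24 min array of BY005 (adjusted p = 0.078) or BY007 (adjusted p = 0.091). Of 20 heat shock factor targets 10 rose and 3 fell (median 0.14), such as SSA4 (1.57 ± 0.08) and YDJ1 (-0.81 ± 0.07). Of 66 mitochondrial ribosomal protein genes 29 rose and 8 fell (median 0.13), such as RSM10 (0.73 ± 0.07) and RSM26 (-0.56 ± 0.05). Among 23 ergosterol genes 10 rose and 5 fell (median 0.13), with ERG28 at 0.76 ± 0.09 and IDI1 at -0.76 ± 0.06. Among 15 glycolysis genes 5 rose and 3 fell, with a median of 0.09 that turned to -0.03 with quantile normalization of the genes alone. TDH1 rose 1.84-fold and the hexokinase gene HXK2 fell 1.31-fold. When adjusted over the list alone the rises and falls were 9 and 2 for heat shock factor targets, 27 and 8 for mitochondrial ribosomal proteins, and 3 and 3 for glycolysis. They were as given above for amino acid permeases, sulfur assimilation, amino acid biosynthesis, ergosterol and the TOR pathway.

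Of 25 G1/S genes 7 rose and 12 fell (median -0.17), such as the ribonucleotide reductase gene RNR1 (-0.67 ± 0.09) and the replication protein gene RFA1 (0.64 ± 0.05), and of 15 G2/M genes 2 rose and 7 fell (median -0.13), such as CLB1 (-0.56 ± 0.12) and KIP2 (0.60 ± 0.07). With spike-in scaling these medians turned to 0.12 and 0.16. Of 21 pheromone response genes 5 rose and 6 fell, with a median of -0.04 that turned to 0.25 with spike-in scaling and to 0.00 with quantile normalization. PRM2 rose by 1.23 ± 0.19 and the kinase gene FUS3 fell by 0.83 ± 0.07. Histone genes rose in 5 of 8 cases (median 0.14), with the linker histone gene HHO1 at 0.65 ± 0.07. Of the 6 reference genes 3 rose and 1 fell. ACT1, for actin, rose by 0.25 ± 0.04 (adjusted p = 0.00036) near the top of the range, while TAF10 fell by 0.34 ± 0.07. Adjusted over the list alone, the counts differed only for pheromone response, with 5 rises and 4 falls.

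In total 2427 genes rose and 1658 fell at 24 min (limma, adjusted p under 0.05), of which 585 and 515 by at least 2-fold. The median of all genes was 0.11. Spike-in scaling raised it by 0.29 and left 1016 rises and 430 falls, with a median standard error of 0.38 per gene against 0.07. Of the 45 genes that had risen at 7 min, 35 had risen at 24 min and 7 were lower than at steady state. The 4 falls at 7 min were falls at 24 min too. Independent lists of these sizes would share 20 rises and 1.22 falls, and 100 simulations of unchanged groups against the same steady-state arrays shared 0, a value that does not measure what the shared arrays add to real effects. Part of the excess may come from the shared steady-state arrays.

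**Figure D4:**
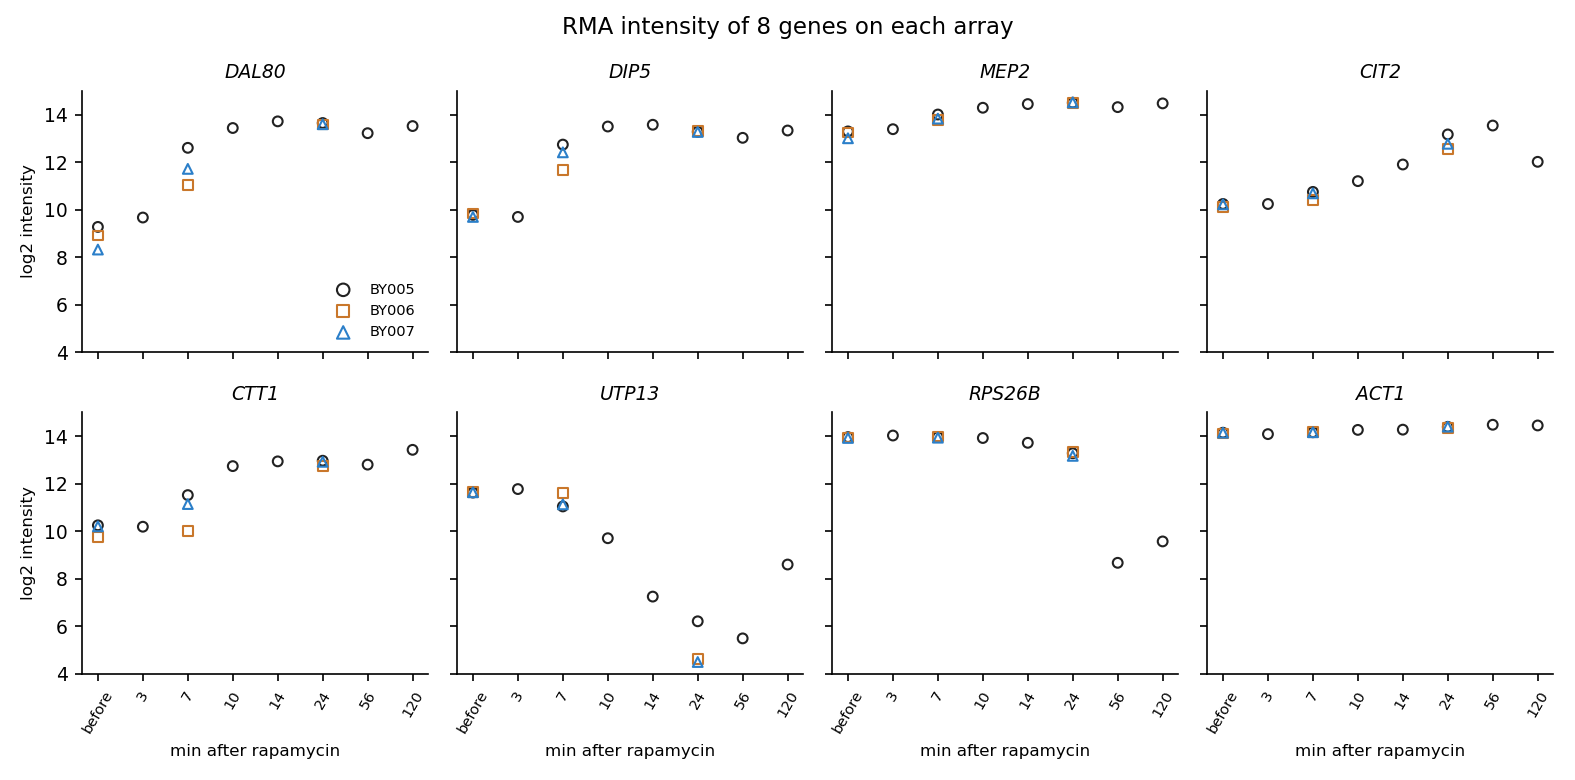
Log2 RMA intensity of 8 genes on each of the 14 arrays, by time after rapamycin and fermentation. DAL80, DIP5 and CTT1 had risen by 10 min, UTP13 fell to 5.11 at 24 min (mean of 3 arrays), and RPS26B stood at 13.27 at 24 min and fell after that, also with spike-in scaling.

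In the direct comparison of 24 with 7 min, MLS1 (4.57 ± 0.23, adjusted p = 4.8e-07), OPT2 (4.49 ± 0.22), GDH3 (4.09 ± 0.24) and GUD1 (3.70 ± 0.22) were higher at 24 than at 7 min, and DBP3 (-5.81 ± 0.31, adjusted p = 7.3e-07), RPA49 (-5.64 ± 0.27), PUF6 (-5.51 ± 0.32) and RPF2 (-5.50 ± 0.24) were lower, as was UTP13, which ended below background. Of the 5449 genes 2153 were higher and 1677 lower at 24 than at 7 min (spike-in scaling 294 and 463). Camera called 12 lists. Those higher were nitrogen catabolite repression (25 rose and 3 fell, adjusted p = 0.00012), retrograde response (7 of 7, adjusted p = 0.00059), stress response (28 of 30, adjusted p = 8.6e-07), trehalose and glycogen (13 of 17, 14 over the list alone, adjusted p = 3e-04), autophagy (25 rose and 2 fell, adjusted p = 8.1e-06), proteasome (32 of 32, adjusted p = 4.4e-06) and respiratory chain (31 rose and 2 fell, adjusted p = 3e-04). Those lower were ribosome biogenesis (98 of 99, adjusted p = 6.5e-33), RNA polymerase I and III (20 of 20, adjusted p = 1.9e-11), cytosolic ribosomal proteins (116 of 128, adjusted p = 2.8e-18), translation factors (26 fell and 1 rose, adjusted p = 1.2e-08) and purine and one-carbon genes (13 of 16, adjusted p = 8.6e-07). Except where given, the counts were the same when adjusted over the list alone. The adjusted p with an estimated correlation lay between 0.23 and 0.51 for these lists. With spike-in scaling the proteasome (adjusted p = 0.11) and respiratory chain (adjusted p = 0.083) were no longer called. The meiosis list (11 of 18 rose, 2 fell) was just past the threshold with the block (adjusted p = 0.048) and not without it.

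At 10 min, on a single array, 29 of 30 nitrogen catabolite repression genes had risen (median 1.62), with DAL80 at 4.60 ± 0.52 and DIP5 at 3.73 ± 0.31, as had 29 of 30 stress response genes (median 1.55) and 17 of 17 trehalose and glycogen genes (median 1.60). Ribosome biogenesis genes had fallen in 85 of 99 cases at 10 min (median -1.26) and in 97 at 14 min (median -2.80). All these medians lay beyond all 10000 random lists. Cytosolic ribosomal protein genes had a median of -0.10 at 10 min, when 17 of 128 had fallen, and of -0.13 at 14 min, when 31 had, both below all 10000 random lists; the latter median turned to 0.34 with spike-in scaling. Pheromone response genes fell in 14 of 21 cases at 14 min (median -0.50), below all 10000 random lists. Of 25 G1/S genes 15 fell (median -0.37, percentile 0.24 among random lists, turned to 0.09 with spike-in scaling). Against the steady-state array of BY005 itself the medians at 14 min were smaller, -0.35 for pheromone response and -0.28 for G1/S. When adjusted over the list alone these counts were 92 for ribosome biogenesis at 10 min, 4 and 13 for ribosomal proteins, 15 for pheromone response and 17 for G1/S, and otherwise the same. Over all genes 1447 rose and 844 fell at 10 min (1232 and 1140 with quantile normalization, 60 and 149 with spike-in scaling), and 1487 rose and 1539 fell at 14 min (363 and 203 with spike-in scaling). Spike-in scaling moved the median of all genes by -0.38 at 10 min and by 0.47 at 14 min.

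At 56 min, on a single array, all 128 ribosomal protein genes were lower than at steady state, with a median of -2.35, also when adjusted over the list alone, and RPS26B stood at -5.28 ± 0.07 (adjusted p = 2.3e-09) and RPL9A, of the large subunit, at -3.57 ± 0.10. Ribosome biogenesis remained low (98 of 99, median -3.69). Purine and one-carbon genes had fallen in 15 of 16 cases (median -1.77). Proteasome genes had a median of 0.74, with 32 of 32 up, and MLS1 was at 6.66 ± 0.32 and GPG1 at 5.30 ± 0.20. The medians of these 4 lists lay beyond all 10000 random lists. Over all genes 2467 rose and 1401 fell, against 436 and 449 with spike-in scaling, and the median of all genes was 0.20.

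At 120 min, HXT5, a hexose transporter gene of slow growth, was up 51.9-fold (5.70 ± 0.29, adjusted p = 6.8e-07), LEE1 48.8-fold, GDH3 45.5-fold, GPG1, a presumed G-protein gamma subunit gene, 42.8-fold, and MLS1 40.2-fold. The largest falls were of the RNA helicase gene DBP2 (55.4-fold, -5.79 ± 0.15, adjusted p = 1.8e-08), the ribose-5-phosphate isomerase gene RKI1 (26.3-fold), NSR1 (20.9-fold), RPL9A and RPS26B (each 20.8-fold). All 30 stress response genes were up, with a median of 2.74 against 1.68 at 24 min. All 128 ribosomal protein genes were down, with a median fall of 4-fold. Ribosome biogenesis genes were down in 96 of 99 cases with a median of -2.20, nearer to steady state than at 24 min. Of 36 respiratory chain genes 34 were up and 1 down (median 0.87). These 4 medians lay beyond all 10000 random lists. Of 21 pheromone response genes 12 were up and 1 down, with a median of 0.40 at percentile 94.67, while the median of all genes was 0.15. These counts were the same when adjusted over the list alone. Over all genes 2254 rose and 1380 fell. Changes between the single arrays were not tested.

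A single test over steady state, 7 and 24 min (limma's moderated F) found 3973 of 5449 genes changed, and 4108 with the fermentation as a block.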

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

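The tests of the 3 patterns below, the spike-in scaling and the spread from the compared arrays alone were chosen only after the result was seen, while the splits of the arrays were planned before.

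A difference between groups drew attention to 7 genes that were above steady state at 7 min and below it at 24 min, each past the threshold at both times, with the step between the times itself tested. From 7 to 24 min, HAP4, a subunit of the activator of respiratory genes, changed by -1.71 ± 0.13, SIT1, a siderophore transporter gene, by -1.284 ± 0.137, and YKR075C, an open reading frame of unknown function, by -2.271 ± 0.126. The permease genes AGP1 (-0.851 ± 0.063), MEP3 (-1.06 ± 0.06) and HXT4 (-0.94 ± 0.08) and the regulator gene VHR1 (-0.636 ± 0.060) fell as well. Under the 3 other scalings 7 of 7 kept the direction of both the rise and the fall, but scaling is not excluded, since with spike-in scaling, whose errors were wide, 0 of 7 did so by more than 2 standard errors and 3 of the steps from 7 to 24 min passed. Chance high values on the 7 min arrays are argued against for 6 of the 7, which were past the threshold above steady state on the separate array at 10 min too, though against the same steady-state arrays; for MEP3, at 0.191 there (adjusted p = 0.1), they stay open. No biological explanation of the rise and fall was tested.

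Signal in data outside the comparisons drew attention to 2 other sets. Of 3470 probe sets with no gene in the annotation used here, 245 changed at 24 min (150 up, 95 down), 139 of them among the 397 above the background percentile. Of 1746 fission yeast probe sets, which serve as background, 36 changed at 24 min (16 up, 20 down), and 7 of these 36 lay above the 95th percentile of the set. None of them changed at 3, 7, 10 or 14 min, while 85 did at 56 min and 67 at 120 min. What these probe sets bound was not tested.

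The arrays taken at 7 min lay at different distances along the response. On a scale where the change of BY005 from steady state to 24 min is 100%, they stood at 21.5% (BY005), 4.44% (BY006) and 16.2% (BY007), each against its own steady state, and without that subtraction the arrays of BY006 and BY007 differed by 11.3%. At steady state BY007 minus BY006 was -0.52%, so these cultures did not lie apart along this direction before the pulse. A prior difference that slowed or weakened the response would not show on this scale and stays open. Steady-state arrays whose hybridisation controls differed by up to 2.28 log2 lay within 0.644%, while the controls of BY006 and BY007 at 7 min differed by 1.73. Steady-state arrays carry no response, so an effect of hybridisation strength on its size could not show there. At 24 min the controls of BY006 and BY007 stood at 8.42 and 10.29, and these arrays lay at 103% and 106%. A difference in effective time cannot be told apart from a weaker early response: across genes the BY007 minus BY006 difference at 7 min followed the change of BY005 from 3 to 10 min (r = 0.734) about as closely as that from steady state to 7 min (r = 0.685).

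Most ribosomal protein genes had fallen by 24 min, but much of their measured fall came later, unlike that of ribosome biogenesis genes. On the array at 56 min 127 of 128 were lower than at 24 min, with a median step of -1.937, which was not tested. Compression at the top of the intensity range cannot be told apart from a real delay: the 32 genes dimmest at steady state stood at -0.840 ± 0.176 (standard error of the median) at 24 min and at -2.902 at 56 min, but at a median level of 13.67 they were still brighter than the ribosome biogenesis genes (11.62), and brighter members fell less (r = 0.664 between level and change). Probe sets shared between paralogs are argued against by the 99 genes without any, with a median of -0.368 ± 0.077 (standard error of the median) at 24 min, where 0.5 times the ribosome biogenesis change would be -1.976. A fault of the array at 56 min is argued against by the array at 120 min, with a median of -2.001, and a biological delay stayed untested.

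For the counts of changed genes, the 6 arrays of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the only one (1 of 10) to give as many genes in each of the comparisons of 7 min, 24 min, and 24 against 7 min: 49, 4085 and 3830, with 0 as the highest among the other splits, both in the 3 that part as many fermentation pairs and in the 6 that part 1 pair. Every other split put arrays of both times into each group, which moves the change between the times into the spread. Their counts of 0 therefore do not show that the real counts exceed chance. For the F test over 9 arrays, 1 of 100 splits drawn from 280 gave 3973 or more, the real one. The highest other, 3879, came from 1 of 2 splits that kept the 24 min arrays together (the lower gave 3819), and the remaining 97 gave 0. Those 97 mixed the 24 min arrays with others, which puts the change at 24 min into the spread. The share therefore rests on the 24 min arrays and does not show a change at 7 min.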

How the results depend on the processing

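The spike-in scaling, the tests on the 2 compared groups alone, the spread without the 7 min arrays, and the other times without the 7 min array of BY005 were added after seeing the data. The count at 7 min (49) was 118 with the fermentation block, 102 with a trended, robust prior, 76 without dim genes, 31 with quantile normalization, 27 with arrays centred, 24 with a 2-fold minimum, 13 with spike-in scaling and 8 from the 2 groups alone, and ran from 7 to 765 with 1 array left out. A 2-fold minimum gave 1100 at 24 min, 867 for 24 against 7 min, 537, 857, 1384 and 1191 at 10, 14, 56 and 120 min, and 1109 for the F test, and spike-in scaling gave 1446, 757, 209, 566, 885, 763 and 1191 in the same order. The spike-in scaling turned DUG3 at 7 min to 0.053. The other counts stayed within 1.5 times, with the block too. The overlap of 7 and 24 min (39) was 103 with the block and 17 with a 2-fold minimum. With an estimated correlation 0 lists passed at 7 min, at 24 min and for 24 against 7 min, and fry gave 4, 25 and 24, against 14, 13 and 12 with camera. Fry asks whether a list changed at all and camera whether it changed differently from other genes, so their counts need not match. Fewer genes can pass a 2-fold minimum, and the cause of the other differences was not tested.

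Of 405 values of named genes at 7, 24 and 120 min, 390 kept their call with the block. With it 9 genes gained a call at 7 min and PFK2 at 120 min, while MET1 lost it at 7 min and UGA4, HHT2, IFH1 and GLN3 at 120 min, and the block changed no other of these calls. Calls were kept by 396 with arrays centred, 394 with quantile normalization and 310 with spike-in scaling, where 93 lost it and 1 gained it. Of 78 list tests the block changed 2, ending heat shock factor targets at 7 min and adding meiosis for 24 against 7 min, and spike-in scaling changed 10. The background at 4.44 (log2) limits falls of dim genes, and the top near 14.84 limits rises and may also shrink falls of bright genes.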

Other observations

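Hexose transporter genes, chosen after their values were seen, moved apart from each other. HXT5 rose to 2.95 ± 0.20 at 24 min and 5.70 ± 0.29 at 120 min. HXT1, for low-affinity uptake, fell by 1.75 ± 0.12 at 24 min (adjusted p = 2.6e-06), and HXT2, for high-affinity uptake, stood at -1.70 ± 0.14 (adjusted p = 6.2e-06) and at -2.09 ± 0.20 at 56 min. HXT3 fell by 0.56 ± 0.05 at 24 min and stood at 0.59 ± 0.07 at 120 min. HXT11 rose by 1.53 ± 0.28 at 24 min, from a level just above background. HXT7, read by a shared probe set, was at 0.85 ± 0.11 at 24 min, -0.59 ± 0.15 at 56 min and 1.17 ± 0.15 at 120 min.

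The next 4 genes were also chosen after their values were seen, because they had risen at 7 min and were not called higher at 24 min. They are not typical of the 45 genes that had risen at 7 min, of which 35 had risen at 24 min too. MTH1, a negative regulator of glucose sensing, rose by 1.15 ± 0.14 at 7 min (adjusted p = 0.011), read -0.28 ± 0.14 at 24 min (adjusted p = 0.093) and stood at 1.93 ± 0.19 at 120 min. HAP4 went from 0.70 ± 0.13 at 7 min to 1.71 ± 0.18 at 10 min, -1.01 ± 0.13 at 24 min and 1.93 ± 0.18 at 120 min. HXT4 was at 1.07 ± 0.12 at 10 min, -0.44 ± 0.08 at 24 min and 1.71 ± 0.12 at 120 min. The maltose permease gene MAL31 rose by 1.07 ± 0.18 at 7 min and read 0.22 ± 0.18 at 24 min (adjusted p = 0.31).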
